A study of Homo sapiens with 4 samples.

How the data were processed

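BFTC905, an established human urothelial carcinoma cell line, was measured in 4 cultures. All cultures had received 10 µg/ml of mitomycin C, a DNA-crosslinking drug used against bladder cancer, for 2.5 h. Per the labels, 2 cultures were then held under a hydrostatic pressure of 10 kPa in a bioreactor and the other 2 (0 kPa) were cultured in the usual way, so the groups differed in the bioreactor as well as in the pressure. RNA was extracted from each culture separately, per the labels' protocols, amplified to Cy3-labelled cRNA and hybridised to 1-colour Agilent arrays. The 4 arrays lay on 1 slide, so no fit with the slide as a block could be made.

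The deposited scanner files held spot intensity values on a linear scale. Per the file headers, they came from Agilent Feature Extraction version 10.5.1.1, which subtracted the background and removed spatial trends within each array, with probe coordinates on hg19. The deposited series table held the same intensity values: the largest relative difference from the processed signal was 0 on each array. Its scale was therefore linear and it was not normalized between arrays. The medians of its 4 columns were 165.8 (0 kPa replicate 1), 317.3 (0 kPa replicate 2), 223.8 (10 kPa replicate 1) and 240.5 (10 kPa replicate 2).

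Control spots and spots marked as non-uniform or population outliers were left out. The processed signal was put on the log2 scale, the 75th percentile of each array was subtracted, and the spots of 1 probe were averaged. Levels are given on this scale, where 0 is the 75th percentile of an array. Of 42405 probes, 36877 (87.0%) were well above background on both arrays of at least 1 group and were tested. Names came from the accessions of the array design where the RefSeq gene table of GRCh38.p14 held them, which was so for 25771 probes. A further 502 were named through an older symbol, and the others kept the name in the files. No coordinate was taken from that table. For each of 29387 names, the brightest tested probe stood for the gene.

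The 10 kPa and 0 kPa groups were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with Benjamini-Hochberg adjustment over all tested probes at a threshold of 0.05. Replicates are separate cultures of 1 cell line, so the limma p-values measure the spread between cultures. Without a block, that spread includes any difference shared by same-numbered cultures. An exact permutation test of 2 against 2 cannot give a two-sided p below 0.333 and was not used. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry beside it, and adjusted over 32 lists of at least 5 tested genes. At the preset correlation camera compares list members with the other genes, so its p-values do not measure the spread between cultures. The comparison, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists covered the YAP/TAZ, TGF-beta, SRF, mechanosensitive, Toll-like receptor, NF-kB, interferon and p53 pathways, crosslink repair, the cell cycle, histones, stress and metabolism, apoptosis, cell identity, growth factors, markers of other cell types, ribosomal proteins and oxidative phosphorylation.

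The rule named TLR6 and CTGF whatever their values, then genes past the threshold, then up to 4 passing members of each list or else the 2 with the largest difference. Where fewer than 6 genes passed in a direction, it was filled to 6 with the smallest unadjusted p among genes well above background on all 4 arrays whose groups did not overlap. As no gene passed, the filled genes and the list members are given as values that did not pass. Alternatives covered background correction, between-array normalization, the filter on dim probes, outlier spots, the variance model, the replicate number as a block, the probe chosen per gene, the set test and leaving out each array.

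The test was first run on simulated arrays with the real probe levels and the fitted spread, for the comparison of 10 kPa with 0 kPa over 36877 probes. It recovered 0 of 67 probes changed 2-fold, 35.8% of 67 changed 4-fold and 78.8% of 66 changed 8-fold, with 3 false calls. Of 32 simulated unchanged lists 0 were called, and a list of 20 probes shifted by 0.4 was called with an adjusted p of 2.28e-09. With a smaller simulated spread, 64.2% of the 67 probes changed 2-fold were recovered, with 4 false calls. In these simulations the probes of a list varied independently. Same-numbered arrays shared no deviation in them, whereas the real replicate differences of the groups correlated at 0.56. Plots were drawn with matplotlib.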

Results

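Gene expression was measured with 1-colour arrays in BFTC905 urothelial carcinoma cells after mitomycin C, in 2 cultures at 0 kPa and 2 cultures under 10 kPa of hydrostatic pressure. The comparison asked which transcripts differed under pressure in drug-treated cells, with TLR6 and CTGF named in the title of the study. The 75th percentile of the processed signal was 872 and 1757 on the 0 kPa arrays and 1197 and 1335 on the 10 kPa arrays. Between 85.9% and 89.3% of probes were well above background on each array, and 0 spots were saturated. Probes spotted 10 times had a median coefficient of variation between 5.46% and 7.48%. The number of arrays limits the precision.

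Both genes named in the title had higher mean signals under pressure, and neither passed the test across all probes. CTGF, now called CCN2, encodes a secreted matricellular protein and is a well-known YAP/TAZ target. Its level was -0.11 ± 0.24 (SD, n = 2) at 0 kPa and 0.67 ± 0.02 (SD, n = 2) at 10 kPa. That is a log2 difference of 0.79 (SE 0.18), or 1.72-fold. TLR6, a cell-surface receptor that pairs with TLR2 to sense bacterial lipopeptides, had a level of -3.11 ± 0.44 (SD, n = 2) at 0 kPa and -2.41 ± 0.31 (SD, n = 2) at 10 kPa. Its log2 difference was 0.70 (SE 0.29), or 1.62-fold. For each gene both pressure arrays lay above both control arrays. The limma adjusted p was 1.00 for both genes over all probes, with unadjusted limma p of 0.00876 for CCN2 and 0.0637 for TLR6. Adjusted over the list alone, these were 0.0175 and 0.0637. The pair was taken from the title of the study, so that adjustment is not treated as independent evidence. The CCN2 probe lies on chromosome 6 at 132270130 to 132270189 and the TLR6 probe on chromosome 4 at 38828533 to 38828592 (hg19), both on the minus strand. Each was the only tested probe of its gene. Without 0 kPa replicate 1 the TLR6 log2 difference was 0.39, but that fit sets unequal replicate numbers against each other. Between same-numbered arrays both genes were higher under pressure in both pairs. TLR6 was -3.43 at 0 kPa and -2.63 at 10 kPa in replicate 1, and -2.80 and -2.20 in replicate 2. For CCN2 the levels were -0.28 and 0.65 in replicate 1, and 0.058 and 0.69 in replicate 2.

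Across all probes, 0 of 36877 passed an adjusted p of 0.05 with limma, and 0 genes passed. At an unadjusted p under 0.05 there were 811 probes, 383 higher and 428 lower under pressure, which is fewer than the 1844 expected by chance. With the replicate number as a block there were 2598. A plain two-group test gave 956 genes at an unadjusted p under 0.05 and 0 after adjustment. With no test, 155 genes had at least a 2-fold difference and groups that did not overlap, 96 of them higher and 59 lower. Among those well above background on all 4 arrays there were 56, and the excess of higher genes was not kept, with 26 higher and 30 lower. Groups did not overlap for 25.3% of all genes, against 33.3% by chance. Without 10 kPa replicate 1 some probes and genes passed, all of them lower, but 10 kPa replicate 2 then stood alone in its group. That array had 52 spots at least 2 log2 units below the same spot on each other array. Between replicate numbers, 97 of the 118 genes called with adjustment over genes were lower in the cultures numbered 2. Whether either underlies the calls was not tested.

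The 6 genes filled in on the higher side were mostly near the dim end of the array. NKX2-1, a lung and thyroid transcription factor, was 2.14-fold higher (SE of the log2 difference 0.15), but its log2 difference was only 0.19 with normexp background correction and 0.14 with quantile normalization as well. The long non-coding RNA LINC00299 differed by 1.21 on the log2 scale, the olfactory receptor genes OR51D1 and OR51I1 by 1.59 and 0.98, and the receptor gene GPRC6A by 0.84. LATS1, a Hippo pathway kinase that restrains YAP, differed by 0.75 (SE 0.15). On the lower side, COPG2IT1 differed by -1.39 (SE 0.14), TMEM100 by -1.30 and LEAP2, which encodes a secreted peptide, by -1.12. RTL10 differed by -0.96, LYG1 by -0.86 and PIWIL4, a member of the Piwi family, by -0.70. Their unadjusted limma p lay between 0.000314 and 0.00538, and none passed the adjustment. With normexp background correction the differences shrank to 0.49 for LINC00299, 0.75 for OR51D1, 0.62 for OR51I1, -0.85 for COPG2IT1, -0.51 for TMEM100, -0.42 for LYG1 and -0.32 for PIWIL4.

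**Figure D1:**
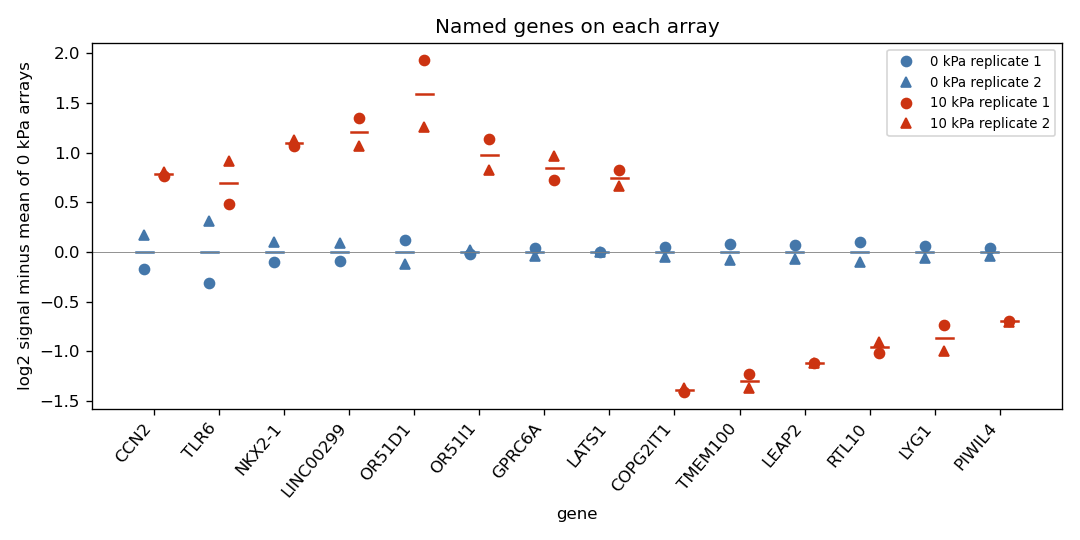
Normalized log2 signal of 14 genes on each of the 4 arrays, relative to the mean of the 0 kPa arrays. Dots and triangles are replicates 1 and 2, and short bars are group means. CCN2 lay 0.79 and TLR6 0.70 above the 0 kPa mean, and COPG2IT1 lay furthest below it, at -1.39.

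Replication-dependent histone genes, which encode the core and linker histones made during DNA synthesis, had mostly higher means under pressure, in 15 of 16 tested members, with a median log2 difference of 0.40. With camera the adjusted p was 3.99e-06, but it was 0.994 with an estimated correlation and 0.994 with fry. H1-3 and H1-4, both linker histone genes, differed by 0.89 (SE 0.58) and 0.66 (SE 0.41). Their values were 0.13 and 0.16 without 10 kPa replicate 1, 0.54 and 0.37 without 0 kPa replicate 2, and 1.66 and 1.16 without 10 kPa replicate 2. No member passed singly, and probes of this family can share signal between near-identical genes. The camera call was lost without 10 kPa replicate 1 (median 0.072) and without 0 kPa replicate 2 (median 0.24). Those fits set unequal replicate numbers against each other, and the list had a median of -0.49 between replicate numbers. Between same-numbered arrays the pressure median was 0.58 for replicate 1 and 0.23 for replicate 2. With the replicate number as a block the camera adjusted p at the preset correlation was 2.51e-08. Neither the estimated correlation nor fry was run with the block. Without 10 kPa replicate 2 the median was 0.76.

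Of the G2/M genes 17 of 20 had higher means, with a median of 0.15. The camera adjusted p was 0.00149, but the adjusted p was 0.994 with an estimated correlation. The mitotic kinesin gene KIF11 differed by 0.31 (SE 0.14) and the spindle checkpoint kinase gene TTK by 0.30 (SE 0.16). The camera call was lost without 10 kPa replicate 1 (median 0.13) and without 0 kPa replicate 2 (median 0.21). It was also lost in the values not normalized between arrays (0.18, adjusted p = 0.196). Between same-numbered arrays the median was 0.23 for replicate 1 and 0.11 for replicate 2. With the replicate number as a block the camera adjusted p at the preset correlation was 0.00385, and the estimated correlation was not run with the block. The S phase genes did not pass, with 18 of 22 higher, a median of 0.068 and an adjusted p of 0.243. Among them CCNE2 differed by -0.20 (SE 0.43) and MCM6 by 0.18 (SE 0.20).

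The third list past the threshold with camera held NF-kB targets and inflammatory genes, with 16 of 22 members higher, a median of 0.15 and an adjusted p of 0.0140, against an adjusted p of 0.994 with an estimated correlation. The cytokine gene IL6 differed by 0.57 (SE 0.15) and the NF-kB inhibitor gene NFKBIA by 0.56 (SE 0.14). The call was lost and the median changed sign without 0 kPa replicate 1 (-0.091) and without 10 kPa replicate 2 (-0.11). The median was 0.49 without 10 kPa replicate 1 and 0.44 without 0 kPa replicate 2. Those fits set unequal replicate numbers against each other, and the list had a median of 0.48 between replicate numbers. Between same-numbered arrays the pressure median was 0.24 for replicate 1 and 0.19 for replicate 2. With the replicate number as a block the camera adjusted p at the preset correlation was 0.00339, and the estimated correlation was not run with the block. The call was also lost in the values not normalized between arrays (0.18, adjusted p = 0.0563). The Toll-like receptors and adaptors did not pass, with 13 of 19 higher, a median of 0.084 and an adjusted p of 0.276. Beside TLR6, IRAK2 had the largest difference, 0.26 (SE 0.50).

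**Figure D2:**
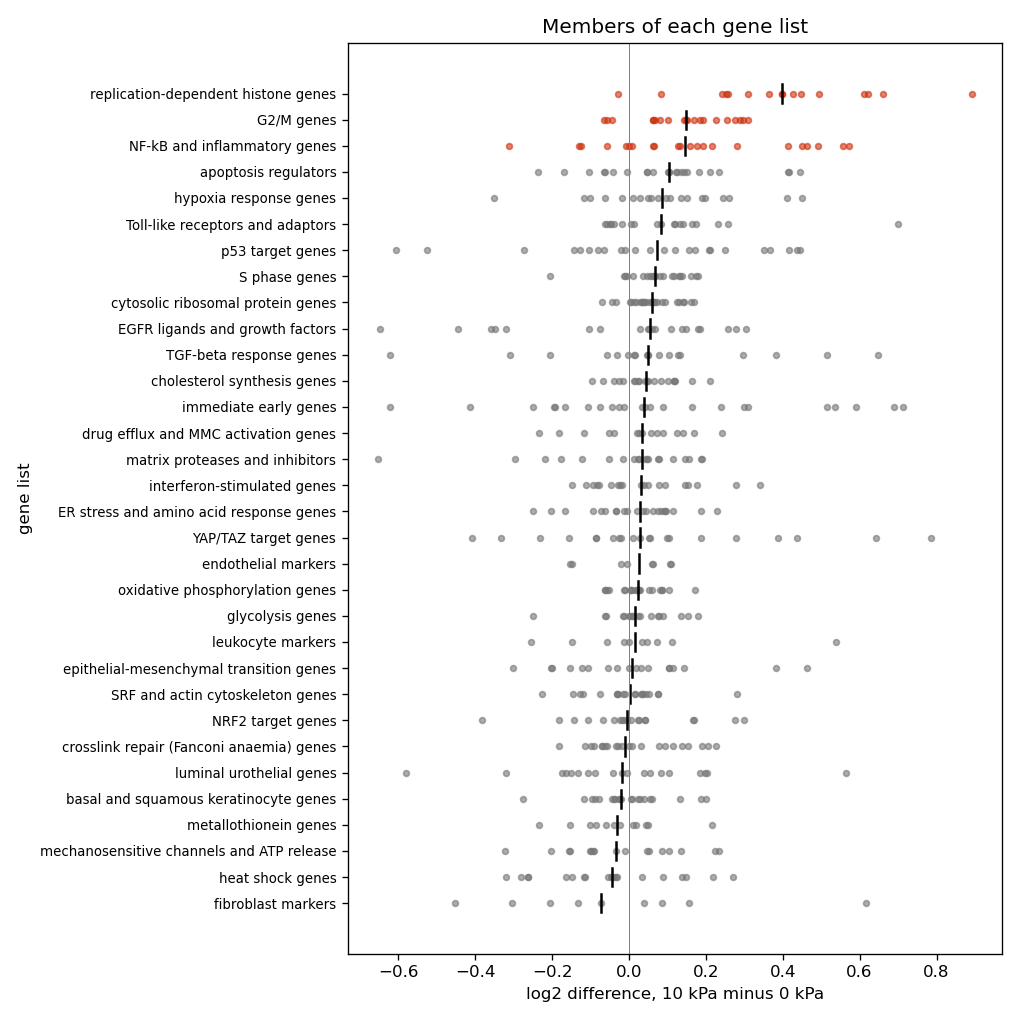
Log2 difference (10 kPa minus 0 kPa) of each tested member of 32 gene lists, with the median of each list as a vertical bar. The histone, G2/M and NF-kB lists, in red, passed the threshold with camera, with medians of 0.40, 0.15 and 0.15, and had an adjusted p of 0.994 with an estimated correlation.

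Lists on mechanical signalling did not pass. Of the YAP/TAZ targets 12 of 21 were higher, with a median of 0.028 and a camera adjusted p of 0.266. With fry the adjusted p was 0.103, the lowest among the lists but also short of the threshold. The list holds CCN2, which the title names. CCN2 had the largest difference and CCN1, its close relative, followed with 0.64 (SE 0.18). The TGF-beta list had 13 of 19 higher and a median of 0.049 (adjusted p = 0.321), with BHLHE40 at 0.65 (SE 0.37) and JUNB at -0.62 (SE 0.26). The SRF and actin list had 10 of 20 higher and a median of 0.0027 (adjusted p = 0.971), with ACTA2 at 0.28 and MYL9 at -0.23. Among mechanosensitive channels and ATP release genes 7 of 17 were higher, with a median of -0.034 (adjusted p = 0.879), TRPV1 at -0.32 and P2RY2 at 0.23. Immediate early genes had 13 of 24 higher and a median of 0.038 (adjusted p = 0.451), with the transcription factor genes KLF6 at 0.71 (SE 0.25) and KLF10 at 0.69 (SE 0.16).

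Lists tied to mitomycin C and cell death did not pass either. The p53 targets had 14 of 24 higher and a median of 0.073 (adjusted p = 0.249), with BTG2 at -0.61 and PLK3 at -0.52. Crosslink repair genes had 10 of 22 higher and a median of -0.0097 (adjusted p = 0.879), with REV3L at 0.23 and SLX4 at 0.21. Apoptosis regulators had 17 of 24 higher and a median of 0.10 (adjusted p = 0.243), with BBC3 at 0.44 and BAX at 0.42. Drug efflux and mitomycin C activation genes had 10 of 15 higher and a median of 0.035 (adjusted p = 0.879), with ABCC4 at 0.24 and MT2A at -0.24. Interferon-stimulated genes had 10 of 19 higher and a median of 0.032 (adjusted p = 0.813), with IFIT3 at 0.34 and IFIT2 at 0.28.

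Stress and metabolic lists stayed short of the threshold. Heat shock genes had 6 of 20 higher and a median of -0.045 (adjusted p = 0.879), with HSPA1B at -0.32 and HSPA2 at -0.28. The ER stress list had 12 of 22 higher and a median of 0.030 (adjusted p = 0.879), with DNAJB9 at -0.25 and TRIB3 at 0.23. Hypoxia genes had 15 of 20 higher and a median of 0.086 (adjusted p = 0.266), with KDM3A at 0.45 and ADM at 0.41. Glycolysis genes had 12 of 18 higher and a median of 0.017 (adjusted p = 0.751), with PFKL at -0.25 and PFKM at 0.18. Cholesterol synthesis genes had 15 of 20 higher and a median of 0.045 (adjusted p = 0.879), with MVK at 0.21 and IDI1 at 0.17. NRF2 targets had 9 of 19 higher and a median of -0.0060 (adjusted p = 0.971), with OSGIN1 at -0.38 and ME1 at 0.30. Metallothionein genes had 5 of 12 higher and a median of -0.031 (adjusted p = 0.971), with MT2A at -0.24 and SLC30A1, a zinc transporter gene, at 0.22.

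Lists on cell identity and matrix gave no call. Luminal urothelial genes had 8 of 19 higher and a median of -0.017 (adjusted p = 0.886), with GRHL3 at -0.58 (SE 0.19) and FOXA1 at 0.56 (SE 0.36). Basal and squamous keratinocyte genes had 10 of 21 higher and a median of -0.021 (adjusted p = 0.886), with KRT16 at -0.28 and DSG3 at 0.20. The epithelial-mesenchymal list had 10 of 18 higher and a median of 0.0091 (adjusted p = 0.971), with ESRP1 at 0.46 and SNAI2 at 0.38. Matrix proteases and inhibitors had 13 of 20 higher and a median of 0.033 (adjusted p = 0.971), with SERPINB2 at -0.65 (SE 0.20) and CTSB at -0.30. EGFR ligands and growth factors had 13 of 20 higher and a median of 0.055 (adjusted p = 0.879), with BTC at -0.65 and BMP4 at -0.45.

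Markers of other cell types and housekeeping lists did not pass. Fibroblast markers had 4 of 9 higher and a median of -0.072 (adjusted p = 0.879), with PDGFRA at 0.62, while LUM was not well above background on either 10 kPa array. Leukocyte and blood markers had 5 of 10 higher and a median of 0.017 (adjusted p = 0.989), with FCGR3A at 0.54 and HBB, an erythroid haemoglobin gene, at -0.26. Endothelial markers had 4 of 8 higher and a median of 0.027 (adjusted p = 0.971), with ESAM at -0.15 and VWF at -0.15. Ribosomal protein genes had 27 of 30 higher and a median of 0.059 (adjusted p = 0.249), with RPL4 at 0.17 and RPLP0 at 0.16. Oxidative phosphorylation genes had 16 of 22 higher and a median of 0.023 (adjusted p = 0.879), with UQCRFS1 at 0.17 and COX5A at 0.10. Median and camera direction had opposite signs for the crosslink repair, basal and squamous, matrix protease and endothelial lists. Median and mean had opposite signs for the SRF and actin, crosslink repair, NRF2, matrix protease and EGFR ligand lists. None of the list members named here passed the adjustment over all probes, and for most of them leaving out 1 array moved the difference by over 1.5 times.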

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

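The variance model with trend and robust settings together with the replicate block, and the set without probes dim on 1 array, were chosen after seeing the data. CTGF (CCN2) and TLR6 kept their direction and stayed short of the threshold under all 14 alternatives, with log2 differences of 0.61 to 0.96 and 0.39 to 1.01 and smallest adjusted p of 0.393 and 0.488. The series table values, not normalized between arrays, gave 13 probes, 9 genes and 9 genes of at least 2-fold past the threshold, and 1 list. Leaving out 1 array gave 0 to 12 probes, 0 to 9 genes, 0 to 9 genes of at least 2-fold and 2 to 9 lists. A 2-fold threshold in place of the test gave 227 genes, and 155 where the groups also did not overlap. Camera with an estimated correlation and fry each called 0 lists, both without the replicate number as a block. With an estimated correlation the camera adjusted p was 0.994 for every 1 of the 32 lists, so it does not tell them apart. For these changes the cause was not tested. A lone array left in a group is assumed to vary like the other group, and its removal also leaves the replicate numbers unequal between the groups. Signal over background limits the dim genes, since 87.0% of probes were tested. The slide as a block was not run, as there was 1 slide.

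The replicate numbers are shared between the groups, but with 2 pairs they are treated as numbers only. The replicate differences of the groups correlated at 0.56 across probes. With the replicate number as a block, 0 probes passed (smallest adjusted p 0.654), 2598 had an unadjusted p under 0.05, against 811 without the block and 1844 by chance, and 3 lists passed; with trend and robust settings as well, 0 probes passed (smallest adjusted p 0.0581). Splitting the 4 arrays by replicate number called 122 probes, where the real split called 0 and the remaining split 0. These counts depend on each other, because without a block the difference between replicate numbers enters the residuals of the other splits. The SD of the log2 differences was 0.40 by replicate number, 0.26 by pressure and 0.21 for the remaining split. Chance cannot be judged from 3 splits.

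Changes of sign concerned values short of the threshold, apart from the NF-kB list and lists called only with an array left out, and their cause was not tested. List medians turned to 0.0011 (crosslink repair), 0.00028 (NRF2) and -0.0046 (endothelial) with normexp; to -0.010 (SRF), 0.0056 (NRF2), -0.024 (epithelial-mesenchymal) and -0.0068 (oxidative phosphorylation) with normexp and quantile normalization; to -0.027 (SRF), -0.0037 (immediate early), -0.0028 (ER stress), -0.0092 (glycolysis), -0.017 (epithelial-mesenchymal) and -0.0049 (oxidative phosphorylation) with quantile normalization. They turned to 0.015 (crosslink repair), 0.019 (NRF2), 0.0076 (luminal) and 0.0036 (basal and squamous) with median scaling, and to 0.021, 0.024, 0.013 and 0.0091 for these lists in the series table values. The fibroblast median was 0.039 with probes well above background on all 4 arrays. With the mean of all probes of a gene, SRF was -0.017 and crosslink repair 0.0034. MVK was -0.22 with outlier spots kept.

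Leaving out 1 array, log2 differences that changed sign ranged from -0.999 to 0.55 for MYL9, -0.32 to 0.84 for IRAK2, -0.65 to 0.24 for CCNE2, -0.025 to 0.39 for MCM6, -0.70 to 0.19 for DNAJB9, -0.17 to 0.63 for TRIB3, -0.84 to 0.34 for PFKL, -0.31 to 0.73 for MVK, -0.46 to 0.79 for IDI1, -0.085 to 0.68 for ME1, -0.062 to 0.95 for BBC3, -0.89 to 0.34 for KRT16, -1.58 to 0.29 for BTC, -0.20 to 1.28 for FCGR3A and -0.30 to 0.0033 for VWF. List medians that changed sign ranged from -0.13 to 0.22 (TGF-beta), -0.14 to 0.11 (SRF), -0.12 to 0.033 (mechanosensitive), -0.024 to 0.14 (Toll-like receptors), -0.11 to 0.49 (NF-kB), -0.070 to 0.075 (interferon), -0.068 to 0.23 (p53), -0.081 to 0.097 (crosslink repair), -0.039 to 0.18 (S phase), -0.30 to 0.37 (immediate early), -0.12 to 0.063 (heat shock), -0.21 to 0.18 (ER stress), -0.095 to 0.25 (hypoxia), -0.043 to 0.12 (glycolysis), -0.34 to 0.41 (cholesterol), -0.30 to 0.37 (NRF2), -0.20 to 0.17 (metallothionein), -0.031 to 0.24 (apoptosis), -0.18 to 0.13 (epithelial-mesenchymal), -0.12 to 0.16 (proteases), -0.039 to 0.098 (drug efflux), -0.14 to 0.022 (luminal), -0.45 to 0.33 (basal and squamous), -0.028 to 0.10 (EGFR ligands), -0.33 to 0.33 (fibroblast), -0.080 to 0.064 (leukocyte), -0.083 to 0.082 (endothelial), -0.095 to 0.21 (ribosomal) and -0.060 to 0.12 (oxidative phosphorylation). The histone and G2/M medians stayed above 0 in each of these. Leaving out 1 array also sets unequal replicate numbers against each other. Between same-numbered arrays, every gene named in this paragraph except FCGR3A kept the sign of the full comparison in both pairs. IDI1, for example, was 1.40 at 0 kPa and 1.59 at 10 kPa in replicate 1. In replicate 2 its levels were 2.65 and 2.80.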

Other observations

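The quantile normalization, brightest-probe and S phase tests in this part were chosen only after the result was seen, as were the comparison between replicate numbers, the interval on the spread of histone families, the unlisted histone median without 1 array and the use of the G2/M list beside the S phase list. That comparison sets both cultures numbered 2 against both numbered 1, irrespective of pressure. With limma, 118 genes passed, 97 lower and 21 higher in the cultures numbered 2. Here the fit and the adjustment ran over 1 probe per gene, not over all tested probes as for pressure. The lower genes included squamous differentiation genes: KRTDAP by -3.52, SBSN by -2.65, KRT1 by -2.71, S100A7 by -2.36, S100A8 by -2.34 and IVL, a cornified envelope precursor, by -2.05 on the log2 scale. The kallikrein genes KLK12 (-3.17), KLK7 (-2.51) and KLK6 (-2.06) were among them too. The cystine transporter gene SLC7A11 was higher by 1.93 and NQO1, a quinone reductase that can activate mitomycin C, by 1.42.

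By list, camera called 16 of 32 between replicate numbers, but with an estimated correlation 0 of 32 passed, with a lowest adjusted p of 0.303. All 20 cholesterol synthesis genes were higher in the cultures numbered 2, with a median of 0.74 and an adjusted p of 8.93e-14. HMGCS1 differed by 1.44 (limma adjusted p = 0.0386) and IDI1 by 1.23, which fell short of the threshold (limma adjusted p = 0.0509). The basal and squamous list had a median of -0.67 (adjusted p = 1.13e-11) and the NRF2 targets one of 0.64 (adjusted p = 1.15e-07). With an estimated correlation each of these 3 had an adjusted p of 0.303. At 0 kPa and 10 kPa the medians were 0.66 and 0.75 for cholesterol synthesis, -0.70 and -0.72 for the basal and squamous genes, and 0.55 and 0.66 for the NRF2 targets. The NF-kB and histone lists, called between pressures, had medians of 0.48 and -0.49 between replicate numbers, both past the threshold with camera but with an adjusted p of 0.446 and 0.499 with an estimated correlation. At 0 kPa and 10 kPa these medians were 0.36 and 0.53 for the NF-kB list and -0.32 and -0.68 for the histone list, and the difference between pressures was not tested.

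A first pattern is that same-numbered cultures deviate together, and 3 technical explanations were tested. A difference in array brightness would give the 0 kPa pair, whose brightness differed by 1.01 on the log2 scale against 0.16 for the 10 kPa pair, at least a 2-fold larger spread of replicate differences, but the ratio was 1.22. An intensity-dependent distortion would vanish on quantile normalization, yet 64.8% of the 122 probes called between replicate numbers were also called after it. Dim probes alone would leave no relation in the brightest probes, where the replicate differences correlated at 0.76 across the probes above the 75th percentile of mean level. The labels say nothing of what the number stands for, so a shared day, passage or density of the cultures may underlie it and was not tested.

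A second pattern is the higher histone list under pressure. The 47 replication-dependent histone genes not on the list had a median of 0.34 and all 47 were higher, which argues against a chance choice of members (one-sided permutation p = 0.0001, the smallest that 10000 random lists can give, with genes taken as independent). This says nothing of the arrays: without 10 kPa replicate 1 the medians of the unlisted and listed genes were 0.095 and 0.072. More cells in S phase or G2/M stays open: the S phase median of 0.068 (SE 0.017) lay below the 0.2 set for it, but the G2/M median was 0.15 (SE 0.033). The SEs of medians in this paragraph come from resampling the genes of a list and leave out the spread between cultures. With 1 array left out the S phase median ran from -0.039 to 0.18. Cross-hybridisation between near-identical histone genes stays open, because the ratio of the spread within families to that between them was 1.08 with a bootstrap interval of 0.69 to 1.49, and so does a shift of all nucleosome genes, because the 8 replication-independent histone genes had a median of 0.10 (SE 0.052), and pressure itself remains an untested explanation.

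The last pattern is spots that were dim on 1 array alone, at least 2 log2 units below the same spot on each other array. There were 95 on 0 kPa replicate 1, 52 on 10 kPa replicate 2, 2 on 10 kPa replicate 1 and 1 on 0 kPa replicate 2. On 0 kPa replicate 1 their median distance to the nearest other such spot was 44.2 pixels, against 110 at the 1st percentile of random spots, and on 10 kPa replicate 2 it was 11.8 against 141. Local defects of the array surface are consistent with this clustering. A transcript missing from 1 sample would lower the other probes of the same genes, but the 51 such probes were lower by a median of only 0.079.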
